A study of Homo sapiens with 4 samples.

How the data were processed

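RNA of 4 samples of PLC/PRF/5 cells, a human liver cancer line, 2 control and 2 with lentiviral USP22 knockdown, was measured by sequencing. Per the labels' protocols, all were kept at 1% oxygen and 5% carbon dioxide for 48 h, RNA was extracted with Trizol, mRNA was isolated, and libraries were made with a kit that does not mark strand (NEBNext Ultra RNA). Reads of a gene and of an antisense or overlapping gene cannot be told apart in such libraries. The control and knockdown libraries were recognised from the sample titles.

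The authors deposited a single table with raw counts for each of the 4 libraries, 14540 rows in all and 1 row per RefSeq mRNA accession. The submitters' processing notes name bcl2fastq, HISAT2 2.1.0 and HTSeq and the build hg19, without saying how each was used. The settings of the counting are not given in the sources used here. The table also holds the authors' log2 fold change, p-value and q-value for knockdown against control. The tool behind these deposited p-values is not given in the sources used here, and the q-values equal a Benjamini-Hochberg adjustment of the p-values to within 6.4e-07. No row summed to less than 14 counts over the 4 libraries, which 62 rows reached.

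Rows of genes with several RefSeq mRNA accessions held few counts. The median row total was 2588 for genes with 1 RefSeq mRNA accession, 311.5 for genes with 2 and 118 for genes with 3 or more. Counting in which reads shared by isoforms of a gene are discarded would give such values, and the rule used is not stated. A row was therefore treated as a transcript rather than a gene. Gene symbols were those of the table. A RefSeq gene table of the assembly GRCh38.p14 was used for the number of accessions per gene and matched 98.5% of the accessions. It also restored 29 symbols that the table held as dates. Because that assembly is not the authors' build, no coordinates are given. Transcript length and GC content came from GENCODE models and were found for 95.9% of the rows.

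Library totals ranged from 15027209 to 17194929 counts. Transcripts were kept by edgeR's filterByExpr with a minimum count of 10, which left 12337 (10780 genes) and removed 2203. TMM normalization factors lay between 0.979 and 1.015. Knockdown minus control was tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all tested transcripts, with a threshold of 0.05. All adjusted p-values of transcripts come from this test unless another is named. The common biological coefficient of variation was 22.1%, and the prior had 11.2 degrees of freedom. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The 2 libraries of a group differed by more than counting noise, with chi-square values per degree of freedom of 19.7 for control and 37.6 for knockdown.

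Before the data were examined, 17 gene lists, the design, most alternatives and a rule for naming genes were fixed. The rule named USP22 and HIF1A, then in each direction the 12 genes with the largest log2 fold change among those past the threshold, with a mean of at least 10 CPM and both knockdown libraries beyond both control libraries. It further named, per list, the 2 members past the threshold with the largest change in each direction. Where no member passed, the 2 members with the highest mean would have been named. Y-linked genes, XIST and genes known only by a clone or locus name were left out. Genes named outside the rule are said to be chosen after their values were seen. Lists were tested with camera (preset correlation 0.01) on 1 row per gene, the accession with the highest total count, with Benjamini-Hochberg adjustment over the 16 lists that could be tested. Of the lists that were tested, 1 list and some genes are not reported here. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera has only the residual degrees of freedom of 4 libraries, so a list can hardly pass it after adjustment over the lists. Not passing there does not show that a list was unchanged. Members past the threshold were counted over all tested transcripts and again adjusted over the list alone. Not every member of a list could be tested. Tested were 16 of 23 stemness genes, 12 of 21 epithelial-mesenchymal transition genes and 8 of 18 markers of other cell types.

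The alternatives fixed in advance were DESeq2 size factors in the edgeR fit, no filter beyond 1 count, a filter of 5 CPM in 2 libraries, the replicate number as a block, leaving out each library in turn, DESeq2, limma-voom, an adjusted p under 0.01 and edgeR's glmTreat against a fold of 1.5. A fit without a library leaves 1 library in an arm, which is then assumed to vary like the other group. Such fits and the block fit estimate the spread from fewer degrees of freedom. Low p-values from them, and low ends of ranges that include them, carry little weight. Rows summed per gene and genes with 1 RefSeq mRNA accession alone were added after seeing the data.

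The procedure was tested on simulated counts drawn from the means and library sizes of these libraries, with 11859 transcripts passing the filter. For the knockdown against control design it recovered 6 of 67 transcripts changed 1.5-fold (8.96%), 25 of 67 changed 2-fold (37.3%) and 52 of 66 changed 4-fold (78.8%). False calls numbered 7, or 7.78% of calls. Far fewer transcripts were changed than the 2304 called in the data. That makes the Benjamini-Hochberg cutoff stricter, so these shares do not measure recovery in the data. Of 16 simulated lists the 1 that was lowered was called, and 0 others were. Transcripts were drawn independently of each other, so this says nothing on lists whose members vary together. The 95% intervals of count ratios are exact binomial intervals and cover counting error only. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.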

Results

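Polyadenylated RNA of PLC/PRF/5 cells, a human hepatocellular carcinoma line, was sequenced after lentiviral knockdown of USP22 and in control cells. USP22 is a ubiquitin-specific protease and a subunit of the SAGA transcriptional coactivator complex, where it removes ubiquitin from histone H2B. All 4 libraries, 2 control and 2 knockdown, came from cells held at 1% oxygen and 5% carbon dioxide for 48 h, so the comparison asked what loss of USP22 did to gene expression in hypoxic liver cancer cells. No normoxic library was analysed here. The control libraries held 15621574 and 16536639 counts and the knockdown libraries 15027209 and 17194929. The 10 most abundant transcripts took 11.068% to 11.965% of the counts of a library. Counts were deposited per RefSeq mRNA accession, called a transcript here, and levels are given as CPM (counts scaled to the TMM-normalized library size), as mean ± SD of 2 libraries. Where a gene has several RefSeq mRNA accessions, the value is that of a single accession. Such genes include LOX, DUOX2, SLC2A2, CYP24A1, CA12, SLC16A3, CPS1, AHSG, BIRC3 and XBP1. They also include ERO1A, VSNL1, ASPM, TTC6, HK2, BMI1, POU5F1, NDUFA4L2, CHAC1, GABARAPL1 and AFP, among others. The labels do not say that replicates were separate cultures. The p-values of transcripts therefore rest on the spread between these libraries, pooled in part over transcripts, and this spread may be technical. Camera with its preset correlation sets the members of a list against the spread over genes, not over cultures.

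The USP22 transcript (NM_015276.1) fell in the knockdown, from 2755 ± 257 to 403 ± 62.1 CPM (n = 2 per group), which left 14.6% of the control level. Its counts were 46513 and 41607 in the control libraries and 5438 and 7683 in the knockdown libraries. The log2 fold change was −2.77 ± 0.17 (SE), a 6.83-fold decrease (6.08 to 7.67 within 1 SE), with a Benjamini-Hochberg adjusted p = 1.36e-06 in edgeR's quasi-likelihood test. The authors' deposited table gives a log2 fold change of −2.75 and a q-value of 4.57e-85 for this transcript. In control cells USP22 ranked 28 by mean CPM among the tested transcripts, and in knockdown cells 429. Rows of genes with several RefSeq mRNA accessions held few counts, which favours its rank. Among the 4471 tested transcripts of genes with 1 accession USP22 ranked 24 in control cells. Other USP family genes with a single RefSeq mRNA accession (11 tested) had a median of 120.2 CPM in control cells and a highest value of 300.5 CPM, that of USP34. HIF1A was not analysed here.

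Between knockdown and control, 2304 of 12337 tested transcripts changed (18.7%). Transcripts that rose numbered 1047, from 1024 genes, and transcripts that fell numbered 1257, from 1229 genes. A fold change of at least 2 was reached by 519 of the transcripts that rose and by 873 of those that fell. Among those with a mean of at least 10 CPM, the transcripts that fell by the largest factors included ENO2 and LOX, and those that rose by the largest factors included RFX6 and ASPM. Both knockdown libraries lay beyond both control libraries for 7353 transcripts (59.6%, against 33.3% by chance for 2 against 2), and 3893 transcripts had an unadjusted p under 0.05 in edgeR's quasi-likelihood test. Log2 CPM values correlated across transcripts, which are not independent replicates, with r = 0.972 within control, 0.977 within knockdown and 0.934 to 0.941 between the groups. Of the 2304 calls, 2253 also had a q-value under 0.05 with the same sign in the authors' deposited table. Another 51 did not, and 0 had the opposite sign. That table holds 3208 rows with a q-value under 0.05, so many of the authors' calls were not called here. Without control replicate 1 the number of transcripts that rose was 685. Tests against a minimum fold change of 1.5 called 254 higher and 583 lower. With the replicate number as a block, a fit with fewer degrees of freedom, 1672 were called higher and 1859 lower.

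**Figure D1:**
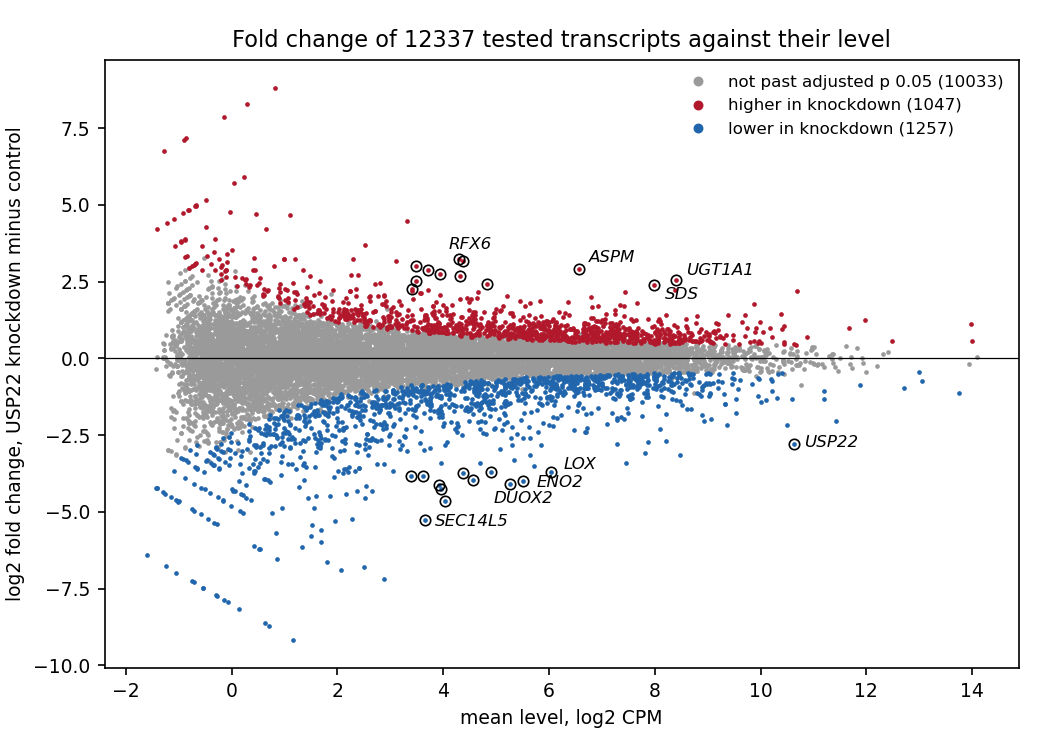
Log2 fold change (USP22 knockdown minus control) of each of 12337 tested transcripts against its mean level in log2 CPM. Red points (1047) rose and blue points (1257) fell at an adjusted p under 0.05, grey points did not pass, and open circles mark USP22, at −2.77, and the 12 named transcripts with the largest change in each direction.

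Among transcripts with a mean of at least 10 CPM, the largest decreases were those of SEC14L5 (log2 fold change −5.27 ± 0.44), NPTX1 (−4.65 ± 0.34), a secreted neuronal pentraxin, and BHLHE41 (−4.27 ± 0.34), a circadian transcriptional repressor. SEC14L5 fell from 24.4 ± 4.46 to 0.641 ± 0.495 CPM (adjusted p = 8.38e-06). NPTX1 fell from 31.4 ± 5.68 to 1.26 ± 0.375 CPM (adjusted p = 3.67e-06) and BHLHE41 from 29.7 ± 3.54 to 1.54 ± 0.62 CPM (adjusted p = 5.33e-06). DUOX2, an oxidase that makes hydrogen peroxide, fell by 4.09 on the log2 scale, from 72.1 ± 11.9 to 4.25 ± 2.31 CPM (adjusted p = 5.88e-06). ENO2, the neuronal form of the glycolytic enzyme enolase, fell from 85.8 ± 3.16 to 5.39 ± 1.36 CPM, a 15.97-fold decrease (adjusted p = 1.36e-06). LOX, which crosslinks collagen, fell from 121 ± 13.9 to 9.37 ± 2.31 CPM, a 12.9-fold decrease (adjusted p = 1.36e-06). SLC8A2, a sodium/calcium exchanger, fell by 3.71 on the log2 scale (adjusted p = 2.77e-06) and TNFRSF9, a member of the tumour necrosis factor receptor family, by 3.74 (adjusted p = 2.27e-05). GPR37L1 (−3.97, adjusted p = 4.22e-06), ARHGEF37 (−3.84, adjusted p = 0.000152) and NCCRP1 (−3.84, adjusted p = 1.54e-05) completed the 12 together with an isoform of DDX41, NM_001321732.1 (−4.11, adjusted p = 5.32e-06). DDX41 has 3 RefSeq mRNA accessions, and this value applies to that row. Leaving out a knockdown library moved the fold of SEC14L5, DUOX2, ARHGEF37 and TNFRSF9 by over 1.5 times. Without knockdown replicate 1 their log2 fold changes were −6.32, −4.74, −5.16 and −4.43, and without knockdown replicate 2 those of SEC14L5 and ARHGEF37 were −4.60 and −3.11.

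Under the same limit on the mean, the 12 largest increases included those of SDS, ADH1A, SLC2A2 and RFX6. SDS, the serine dehydratase that degrades serine to pyruvate, rose from 81.7 ± 30.6 to 425 ± 79.7 CPM (log2 fold change 2.38 ± 0.24, adjusted p = 3.80e-05). ADH1A, an alcohol dehydrogenase, rose 7.98-fold, to 19.98 ± 6.09 CPM (adjusted p = 7.34e-05). SLC2A2, the glucose transporter of hepatocytes, rose from 5.39 ± 2.02 to 34.4 ± 7.77 CPM (2.67 ± 0.31, adjusted p = 0.000101). UGT1A1, which conjugates bilirubin, rose from 97.2 ± 32.2 to 576 ± 47.1 CPM (2.57 ± 0.22, adjusted p = 8.50e-06), but it shares exons with the other UGT1A genes and its value is uncertain. CYP24A1, which inactivates vitamin D, rose by 2.43 on the log2 scale (adjusted p = 2.27e-05), and the aldo-keto reductase AKR1B10 by 2.87 (adjusted p = 0.000488). Among transcripts with a mean of at least 10 CPM and groups that did not overlap, the largest increase was that of RFX6, a transcription factor of pancreatic endocrine development, from 3.78 ± 0.63 to 35.5 ± 5.49 CPM (3.23 ± 0.28, adjusted p = 9.74e-06). VSNL1, a neuronal calcium sensor, rose by 3.17 (adjusted p = 4.19e-05), and ASPM, a protein of the mitotic spindle, rose from 21.9 ± 3.55 to 167 ± 33.8 CPM (2.93 ± 0.21, adjusted p = 4.02e-06). The collagen gene COL3A1 (2.74, adjusted p = 0.00174), TTC6 (2.28, adjusted p = 0.000221) and an isoform of DFFA, NM_213566.1 (2.53, adjusted p = 0.000916), were the others of the 12. Without control replicate 2 the log2 fold changes of AKR1B10, COL3A1 and DFFA were 3.94, 3.73 and 3.50. Without control replicate 1 that of AKR1B10 was 2.28, and without knockdown replicate 1 that of COL3A1 was 1.98.

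Most of the tested genes known to be induced by hypoxia fell in the knockdown. The list was lower than other genes by camera with its preset correlation (adjusted p = 8.05e-28). It did not pass with the correlation estimated from these 4 libraries (adjusted p = 0.18 with an estimated correlation). The estimated correlation was 0.0959 against the preset 0.01, which raises the p-value as well. The setting also has few degrees of freedom with 4 libraries, so a list can hardly pass it after adjustment, here or below. Of the 30 hypoxia targets of the list 25 could be tested. Of these 19 fell, 0 rose and 6 did not pass, with a median log2 fold change of −2.05. Adjusted over the list alone, 22 fell and 0 rose. The largest decreases were those of LOX and of CA12, a membrane carbonic anhydrase, which was near the detection limit with 32 and 46 counts in control and 2 and 5 in knockdown libraries (log2 fold change −3.46 ± 0.76, adjusted p = 0.00684, and −4.11 without knockdown replicate 2). More abundant members, chosen after their values were seen, fell as well. CA9, another carbonic anhydrase, fell from 1078 ± 172 to 240.3 ± 18.3 CPM (adjusted p = 5.32e-06), and BNIP3, a mitophagy receptor, from 2354 ± 95.3 to 526 ± 13.8 CPM (adjusted p = 2.44e-06). ERO1A, an oxidase of the endoplasmic reticulum, fell from 4459 ± 222 to 1075 ± 176 CPM (adjusted p = 5.18e-06). DDIT4 and BHLHE40, chosen in the same way, did not pass (adjusted p = 0.908 and 0.322), and their knockdown libraries stood apart. DDIT4 had 1171 and 472 CPM in knockdown replicates 1 and 2 against 754 and 815 CPM in control, and BHLHE40 had 1209 and 355 CPM against 1099 and 1209 CPM. Knockdown replicate 1 was also the higher for ADM, HILPDA and ANKRD37, while the list median relative to control was −1.82 in knockdown replicate 1 and −2.17 in knockdown replicate 2.

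Genes of glucose uptake and glycolysis fell in part. Of 18 tested, 8 fell, 1 rose and 9 did not pass, with a median log2 fold change of −0.92, and adjusted over the list alone 11 fell and 1 rose. The largest decreases were those of ENO2 and of SLC16A3, the lactate exporter MCT4, which had 43 and 40 counts in control and 4 and 3 in knockdown libraries (−3.53 ± 0.72, adjusted p = 0.00462). HK2, a hexokinase chosen after its values were seen, fell from 322 ± 2.19 to 30.5 ± 15.4 CPM (adjusted p = 7.47e-06). PGK1, whose row had the highest CPM among the rows of the list, also chosen after its values were seen, fell from 8878 ± 222 to 4541 ± 364 CPM (adjusted p = 0.000369). The row of PFKM, the muscle form of phosphofructokinase and a gene with 20 RefSeq mRNA accessions, rose (1.25 ± 0.35, adjusted p = 0.0268). With rows summed per gene PFKM did not pass (0.79, adjusted p = 0.0816). The call of the row was also lost without control replicate 1 (adjusted p = 0.117) and without knockdown replicate 2 (adjusted p = 0.119), over a range of 0.00291 to 0.13 across 12 alternatives. The glycolysis list was lower than other genes (camera adjusted p = 7.56e-09), but adjusted p = 0.18 with an estimated correlation. GAPDH, LDHA and PKM, also chosen after their values were seen, had 18.4, 2.00 and 2.44 CPM in control cells, and these low rows of genes with several accessions say little on the expression of the genes.

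**Figure D2:**
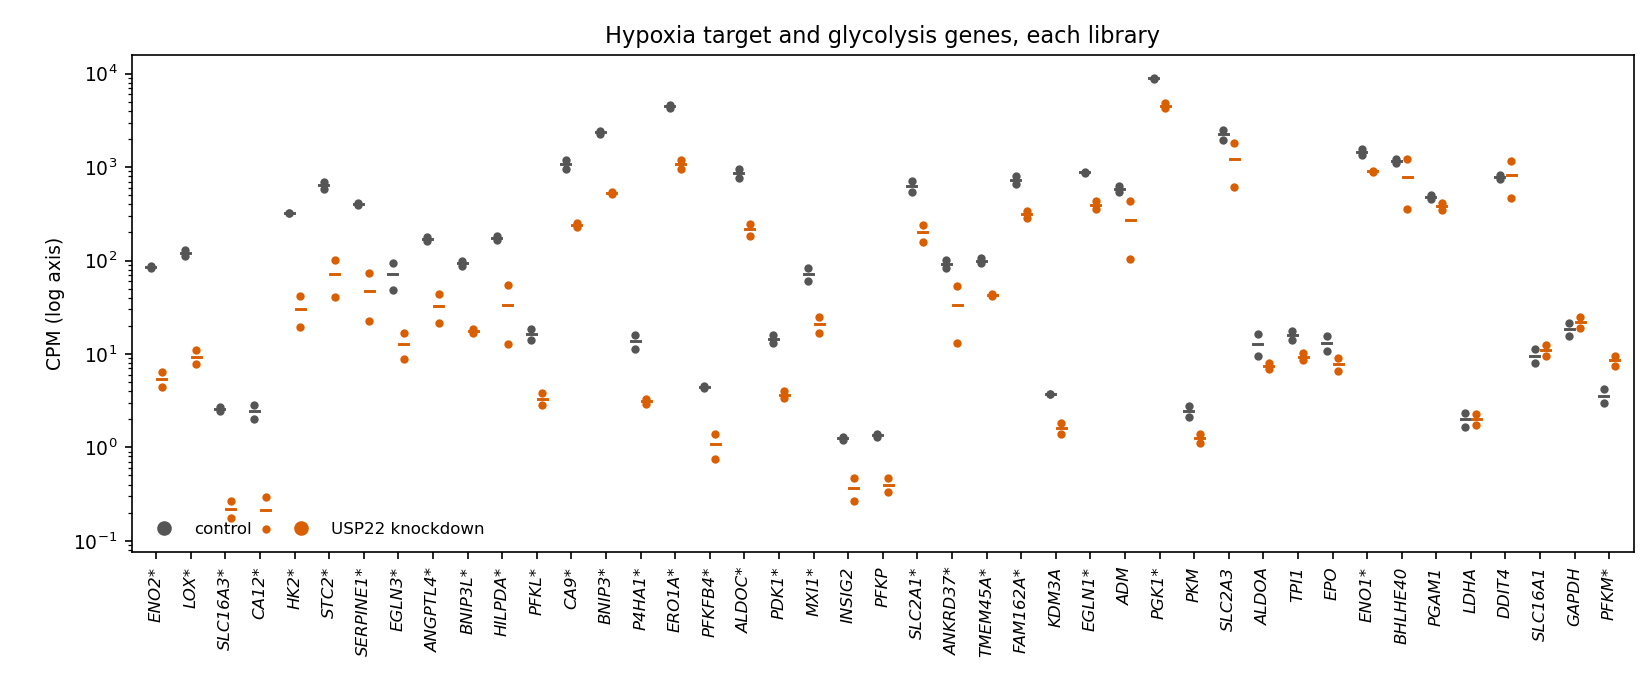
CPM (log axis) of the tested hypoxia target and glycolysis genes in each library, ordered by log2 fold change, with control libraries in grey, knockdown libraries in orange, bars at the group means and an asterisk on genes that passed an adjusted p of 0.05. From ENO2, at 85.8 against 5.39 CPM, through PGK1, at 8878 against 4541 CPM, most genes with an asterisk lie lower in the knockdown, and PFKM lies higher.

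Cell cycle genes rose in part. Of 29 tested, 16 rose, 1 fell and 12 did not pass, with a median log2 fold change of 0.87. Adjusted over the list alone 18 rose and 1 fell. E2F1, chosen after its values were seen, did not pass at 261 CPM in control cells. FOXM1 and AURKA, chosen likewise, did not pass at 1.48 and 2.66 CPM. Such low rows of genes with several accessions say little on the expression of the genes. The centromere protein gene CENPF rose from 117 ± 44.5 to 554 ± 228 CPM (2.24 ± 0.29, adjusted p = 0.000192), and the mitotic kinesin gene KIF20A from 44.7 ± 7.91 to 178 ± 6.85 CPM (1.99 ± 0.19, adjusted p = 2.27e-05). TOP2A, a topoisomerase of dividing cells chosen after its values were seen, rose from 489 ± 23.9 to 1112 ± 158 CPM (adjusted p = 0.000286). CCNE2, a cyclin of the G1 to S transition, fell from 38.1 ± 2.68 to 17.1 ± 1.14 CPM (−1.15 ± 0.22, adjusted p = 0.00313). The list was higher than other genes (camera adjusted p = 5.88e-10), with adjusted p = 0.293 with an estimated correlation.

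Genes of the hepatocyte list rose in part. Of 24 tested, 9 rose, 1 fell and 14 did not pass, with a median log2 fold change of 0.40, and adjusted over the list alone 10 rose and 2 fell. The tyrosine aminotransferase TAT rose from 9.46 ± 1.32 to 36.4 ± 3.26 CPM (1.94 ± 0.24, adjusted p = 0.000174). CPS1, the entry enzyme of the urea cycle, rose from 41.7 ± 4.91 to 116 ± 11.2 CPM (1.47 ± 0.19, adjusted p = 0.000195). The members that rose, named after their values were seen, also included alpha-fetoprotein (AFP) and the fibrinogen genes FGA, FGB and FGG. AFP rose from 370 ± 90.9 to 806 ± 42.7 CPM (adjusted p = 0.00102). The rise of the list is therefore not one of genes of mature hepatocyte function alone. AHSG, a secreted plasma glycoprotein, fell (−0.92 ± 0.20, adjusted p = 0.00709), and its call was lost without control replicate 2 (−0.51, adjusted p = 0.154, over a range of 1.53e-09 to 0.154 across 12 alternatives). Albumin (ALB), chosen after its values were seen, had 726 ± 98.2 CPM in control and 641 ± 132 CPM in knockdown cells and did not pass (adjusted p = 0.538). The list was higher than other genes (camera adjusted p = 0.00147), but adjusted p = 0.297 with an estimated correlation and 0.145 among genes with 1 RefSeq mRNA accession. By fry, which tests a list against no change, it did not pass (adjusted p = 0.0543).

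**Figure D3:**
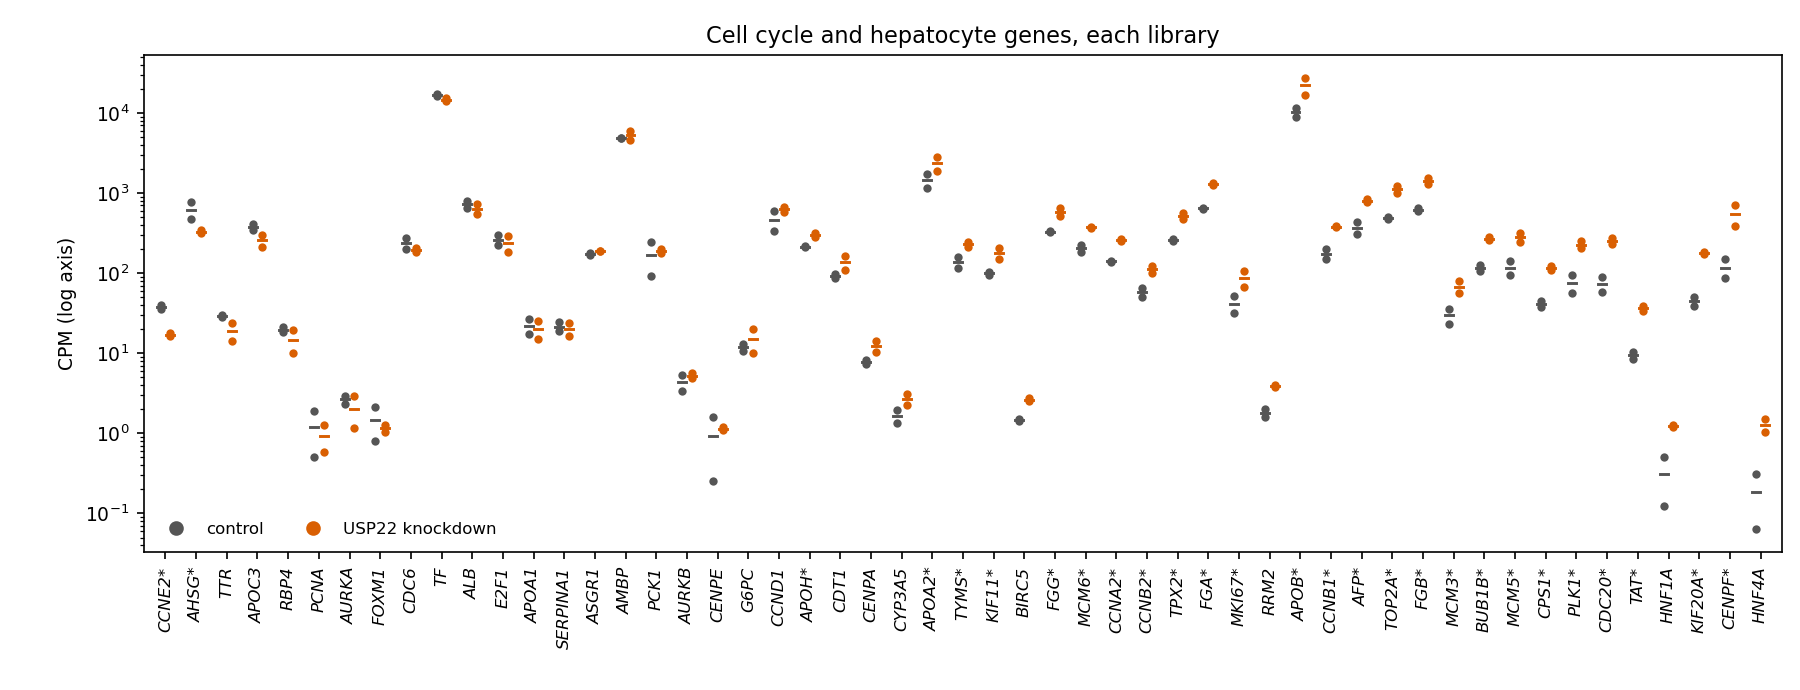
CPM (log axis) of the tested cell cycle and hepatocyte genes in each library, drawn and ordered as in the plot of hypoxia target genes. CENPF, at 117 against 554 CPM, and TAT, at 9.46 against 36.4 CPM, are among the genes that lie higher in the knockdown, and CCNE2 and AHSG lie lower.

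Inflammatory genes driven by NF-kB fell in part. Of 15 tested, 9 fell, 0 rose and 6 did not pass, with a median log2 fold change of −1.14, and adjusted over the list alone 11 fell and 0 rose. BIRC3, an inhibitor of apoptosis, fell from 174 ± 23.0 to 36.4 ± 18.2 CPM (−2.26 ± 0.28, adjusted p = 0.000152, and −2.85 without knockdown replicate 1). The row of the mitochondrial superoxide dismutase SOD2, an isoform (NM_001322816.1), fell from 10.8 ± 6.03 to 2.47 ± 1.18 CPM (−2.13 ± 0.46, adjusted p = 0.0062, and −1.40 without control replicate 1). CXCL8, a neutrophil chemokine chosen after its values were seen, fell from 227 ± 122 to 65.9 ± 13.5 CPM (adjusted p = 0.00123). The list was lower than other genes (camera adjusted p = 6.96e-07), but adjusted p = 0.293 with an estimated correlation and 0.0715 among genes with 1 RefSeq mRNA accession.

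Genes of the unfolded protein and integrated stress response fell in part. Of 21 tested, 10 fell, 2 rose and 9 did not pass, with a median log2 fold change of −0.43, and adjusted over the list alone 11 fell and 2 rose. PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2α, fell from 249 ± 14.7 to 61.8 ± 5.37 CPM (−2.01 ± 0.17, adjusted p = 9.32e-06). CHAC1, which degrades glutathione, fell from 55.4 ± 0.196 to 16.1 ± 0.611 CPM (−1.78 ± 0.21, adjusted p = 0.000116). XBP1, a transcription factor of the unfolded protein response, rose from 40.1 ± 0.501 to 78.0 ± 3.12 CPM (0.96 ± 0.19, adjusted p = 0.00316). SDF2L1, a protein of the endoplasmic reticulum, rose (0.79 ± 0.23, adjusted p = 0.0287), and its call was lost without control replicate 1 (0.49, adjusted p = 0.249, over a range of 6.13e-07 to 0.369 across 12 alternatives). The list was lower than other genes (camera adjusted p = 5.47e-05), but adjusted p = 0.361 with an estimated correlation. By fry it did not differ from no change at the threshold (adjusted p = 0.0543).

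Most autophagy and lysosome genes did not pass, and the list was lower by a narrow margin that several alternatives did not keep. Of 12 tested, 2 fell, 0 rose and 10 did not pass, with a median log2 fold change of −0.34, and adjusted over the list alone 2 fell. MAP1LC3B, the autophagosome protein LC3B, fell from 744 ± 24.4 to 208 ± 4.70 CPM (−1.84 ± 0.16, adjusted p = 8.50e-06). GABARAPL1, a related protein, fell from 265.7 ± 0.0657 to 158 ± 12.02 CPM (−0.75 ± 0.16, adjusted p = 0.00588). The list passed by camera (adjusted p = 0.0469), but adjusted p = 0.316 with an estimated correlation. It also did not pass without control replicate 1, control replicate 2 or knockdown replicate 1. The camera adjusted p was 0.0554 with the replicate block, 0.0615 without the filter and 0.0688 with the stricter filter. Among genes with 1 RefSeq mRNA accession it was 0.145. The list passed without knockdown replicate 2, with DESeq2 size factors (camera adjusted p = 0.049), with rows summed per gene (0.0304) and by fry (0.0396).

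The SAGA complex list, which holds USP22 itself, did not pass by camera. Of 18 tested, USP22 included, 2 fell, 1 rose and 15 did not pass, with a median log2 fold change of −0.39. Adjusted over the list alone 2 fell and 2 rose. TADA2B, chosen after its values were seen, did not pass at 143 CPM in control cells. ATXN7, TADA3 and TRRAP, chosen likewise, did not pass at 1.56, 1.16 and 1.56 CPM. Such low rows of genes with several accessions say little on the expression of the genes. KAT2B, an acetyltransferase that can serve in SAGA, fell from 48.0 ± 1.104 to 26.4 ± 1.80 CPM (−0.86 ± 0.20, adjusted p = 0.0106), but not past the threshold without control replicate 1 (adjusted p = 0.0622, over a range of 0.000137 to 0.218 across 12 alternatives). TAF6L, a structural subunit, rose from 36.7 ± 3.83 to 60.3 ± 8.70 CPM (0.72 ± 0.20, adjusted p = 0.0264). Its call was lost without control replicate 1 (adjusted p = 0.194), control replicate 2 (adjusted p = 0.0535) or knockdown replicate 2 (adjusted p = 0.0953), over a range of 0.000774 to 0.454 across 12 alternatives. The camera adjusted p was 0.15, and adjusted p = 0.361 with an estimated correlation, while the list passed by fry (adjusted p = 0.0452). The list was not tested without USP22.

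Genes used as markers of liver cancer stem cells moved in both directions. Of 16 tested, 2 rose, 3 fell and 11 did not pass, and adjusted over the list alone 3 rose and 3 fell. ALDH1A1, an aldehyde dehydrogenase, rose from 2388 ± 234 to 5705 ± 789 CPM (1.26 ± 0.15, adjusted p = 0.000132). BMI1, a Polycomb protein, rose from 10.6 ± 0.64 to 21.1 ± 2.62 CPM (1.00 ± 0.26, adjusted p = 0.0157), with the call lost without control replicate 1 (adjusted p = 0.0813) or knockdown replicate 2 (adjusted p = 0.051), over a range of 0.00085 to 0.16 across 12 alternatives. POU5F1, the pluripotency factor OCT4, fell from 7.11 ± 2.27 to 1.502 ± 1.05 CPM (−2.25 ± 0.50, adjusted p = 0.00715). POU5F1 has near-identical pseudogenes, so its value is uncertain, and it was −3.18 without knockdown replicate 1 and −1.65 without knockdown replicate 2. EPCAM, an epithelial adhesion molecule, fell from 25 and 62 counts to 11 and 7 (−2.25 ± 0.68, adjusted p = 0.0352). The call of EPCAM was lost without control replicate 2 (−1.46, adjusted p = 0.334) or knockdown replicate 2 (adjusted p = 0.123), over a range of 0.00193 to 0.334 across 11 alternatives. The list did not pass (camera adjusted p = 0.613, and adjusted p = 0.845 with an estimated correlation), with a median log2 fold change of 0.13 and a mean of −0.04, which differ in sign. CD44, another such marker, was not analysed here.

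Most cholesterol and fatty acid synthesis genes did not pass. Of 18 tested, 5 fell, 1 rose and 12 did not pass, with a median log2 fold change of −0.34, and adjusted over the list alone 6 fell and 1 rose. SCD, the stearoyl-CoA desaturase, fell from 18995 ± 2560 to 8737 ± 2281 CPM (−1.12 ± 0.17, adjusted p = 0.000782). Fatty acid synthase (FASN) rose from 2192 ± 489 to 4326 ± 249 CPM (0.98 ± 0.17, adjusted p = 0.00135). The list did not pass (camera adjusted p = 0.273, and adjusted p = 0.628 with an estimated correlation) except without control replicate 2 (adjusted p = 0.0499).

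The other lists did not pass. Among 15 interferon-stimulated genes 2 fell, 0 rose and 13 did not pass (median −0.10), and adjusted over the list alone 2 fell. The camera adjusted p was 0.446, and adjusted p = 0.845 with an estimated correlation. ISG15, a ubiquitin-like protein, fell from 219 ± 24.7 to 108 ± 4.04 CPM (−1.02 ± 0.17, adjusted p = 0.00119). MX2, an antiviral GTPase, fell from 40 and 21 counts to 2 and 1 (adjusted p = 0.00684), a ratio of 20.4 with an exact 95% counting interval of 6.65 to 102. Its call was lost without control replicate 1 (adjusted p = 0.0615, over a range of 0.00063 to 0.0615 across 11 alternatives). Its fitted log2 fold change was −4.24, and −4.83 without knockdown replicate 1. Of 13 Wnt/β-catenin targets 1 rose, 0 fell and 12 did not pass (median 0.44), and adjusted over the list alone 0 rose and 0 fell. Their camera adjusted p was 0.197, with adjusted p = 0.546 with an estimated correlation and 0.0349 without control replicate 2. DKK1, a secreted Wnt antagonist, rose from 0 and 5 counts to 13 and 49 (adjusted p = 0.0352), with the call lost without control replicate 1 (adjusted p = 0.0572) or knockdown replicate 2 (adjusted p = 0.481), over a range of 0.000518 to 0.481 across 11 alternatives. Its fitted log2 fold change was 3.52 ± 1.07. It was 2.57 without control replicate 1, 4.17 without knockdown replicate 1 and 2.42 without knockdown replicate 2. Without control replicate 2 the control held 0 counts, so the fitted value of 7.92 was set by the prior count.

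Of 12 epithelial-mesenchymal transition genes 1 fell, 0 rose and 11 did not pass, and adjusted over the list alone 1 fell. The gene was ITGA5, the fibronectin receptor subunit integrin α5, which fell from 3365 ± 28.7 to 1342 ± 73.4 CPM (−1.33 ± 0.14, adjusted p = 5.60e-05). The median (0.05) and mean (0.03) of the list were positive while camera placed it lower (adjusted p = 0.808, and adjusted p = 0.954 with an estimated correlation). Of 21 oxidative phosphorylation genes 1 rose, 1 fell and 19 did not pass, and adjusted over the list alone 0 rose and 1 fell. Their median was 0.12, their mean −0.11 and their camera adjusted p 0.772, with adjusted p = 0.954 with an estimated correlation. NDUFA4L2, a paralogue of a respiratory chain subunit, fell from 45 and 60 counts to 9 and 6 (−2.79 ± 0.61, adjusted p = 0.00661). CYC1, cytochrome c1, rose from 434 ± 22.3 to 634 ± 141 CPM (0.55 ± 0.17, adjusted p = 0.0447). The CYC1 call was lost without control replicate 1 (adjusted p = 0.196), control replicate 2 (adjusted p = 0.0798) or knockdown replicate 2 (0.31, adjusted p = 0.276), over a range of 2.73e-05 to 0.808 across 12 alternatives.

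Markers of other cell types served as a check of the samples. Of 8 tested, 2 rose, 1 fell and 5 did not pass, and adjusted over the list alone 2 rose and 1 fell. Their median (−0.37) and mean (−0.58) were negative while camera placed the list higher (adjusted p = 0.964, and adjusted p = 0.967 with an estimated correlation). COL3A1, a fibrillar collagen of fibroblasts, rose as given above. PECAM1, an endothelial adhesion molecule, rose from 12.4 ± 3.32 to 25.3 ± 4.19 CPM (1.02 ± 0.27, adjusted p = 0.0185), with the call lost without control replicate 2 (adjusted p = 0.137, over a range of 0.000208 to 0.16 across 12 alternatives). The haemoglobin gene HBB fell from 45 and 40 counts to 0 and 1 (adjusted p = 0.0011), a ratio of 85.2 with an exact 95% counting interval of 14.9 to 3400. Its fitted log2 fold change, which at such counts depends on the prior count, was −6.11, against −5.30 without knockdown replicate 1 and −8.39 without knockdown replicate 2. The mitochondrially encoded list had 0 transcripts in the table.

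**Figure D4:**
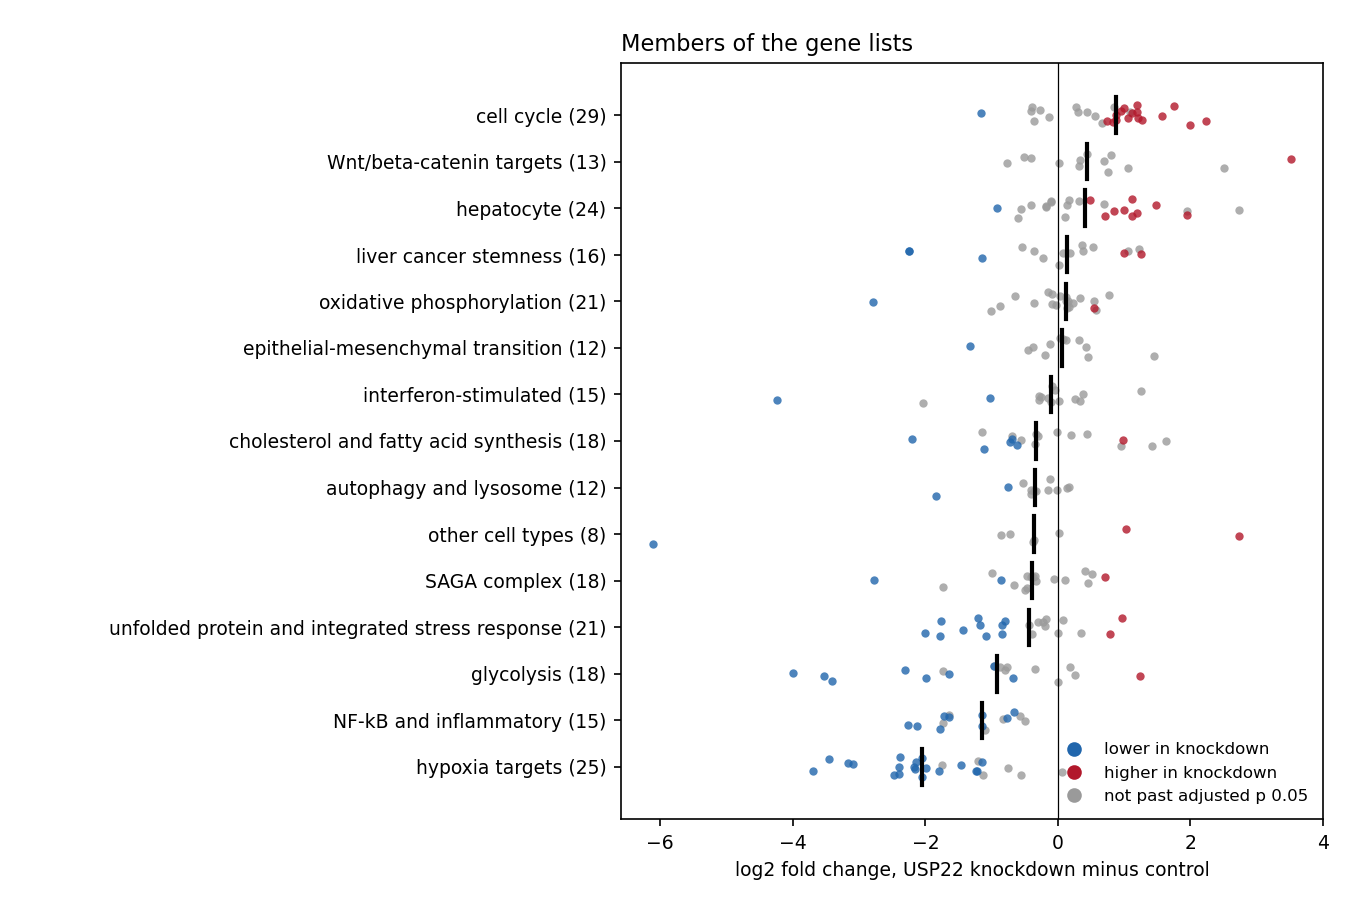
Log2 fold change (USP22 knockdown minus control) of each tested member of 15 gene lists, with the number tested in brackets and a black bar at the list median. The hypoxia target list lies lowest, with a median of −2.05, and the cell cycle list highest, with a median of 0.87.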

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

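The tests on rows summed per gene and on genes with 1 RefSeq mRNA accession were chosen after seeing the data. USP22 stayed lower and past the threshold in all 12 alternatives, with log2 fold changes from −2.93 to −2.58. No transcript called in the main test changed sign in an alternative that tested it. With the stricter filter 134 calls that rose and 289 that fell had no test. With rows summed per gene these were 68 and 65. Of all calls, 54.6% were lower in the main test, 53.7% with DESeq2 size factors and 69.65% by glmTreat. The share was 60.15% without control replicate 1 and 49.18% without knockdown replicate 1, where 1340 rose and 1297 fell, so the direction with more calls turned without that library. The numbers of transcripts that rose and fell were 254 and 583 by glmTreat and 433 and 686 at an adjusted p under 0.01, since both thresholds are stricter, and 685 to 1340 rose when a library was left out, the lowest without control replicate 1. With the replicate number as a block 1672 rose and 1859 fell, and the autophagy list had an adjusted p of 0.0554. The block changed no other list call. Same-numbered libraries deviated together with r = 0.112 over all tested transcripts and 0.258 over those of at least 10 CPM, and with 2 pairs the numbers do not establish pairing. With an estimated correlation 0 of 16 lists passed. The adjusted p was 0.18 for hypoxia targets and for glycolysis, 0.297 for hepatocyte genes and 0.293 for cell cycle and for NF-kB genes. It was 0.361 for the stress response and 0.316 for autophagy. The estimated correlation was −0.0471 for glycolysis and −0.088 for autophagy, under the preset 0.01, so correlation did not raise their values. That setting has few degrees of freedom with 4 libraries, so a list can hardly pass it. By fry, which does not compare a list with other genes, the values were 0.0543 for hepatocyte and stress response genes, 0.0452 for SAGA, and 0.873 for other cell types, whose direction turned. Among genes with 1 RefSeq mRNA accession they were 0.145 for hepatocyte and autophagy genes and 0.0715 for NF-kB genes, with fewer members tested. The autophagy list had 0.0615 without the filter and 0.0688 with the stricter filter, and the list of other cell types turned to lower without the filter (0.635). When a library was left out the adjusted p ranged from 0.278 to 0.705 for stemness genes, from 0.0499 to 0.726 for cholesterol and fatty acid synthesis, from 0.343 to 0.721 for epithelial-mesenchymal transition, from 0.0349 to 0.299 for Wnt targets, from 0.279 to 0.953 for oxidative phosphorylation, from 0.0312 to 0.127 for autophagy and from 0.423 to 0.614 for other cell types. Autophagy did not pass without control replicate 1, control replicate 2 or knockdown replicate 1. Cholesterol synthesis and Wnt targets passed without control replicate 2. Directions turned, without passing, for stemness without control replicate 1 (0.705), for epithelial-mesenchymal transition without control replicate 2 (0.653) or knockdown replicate 2 (0.721), for oxidative phosphorylation without knockdown replicate 2 (0.953) and for other cell types without control replicate 1 (0.423) or knockdown replicate 1 (0.614). Over the 12 alternatives of each list the lowest and highest adjusted p were 1.49e-42 and 0.18 for hypoxia targets, 8.01e-11 and 0.18 for glycolysis, 9.41e-05 and 0.297 for hepatocyte genes, 2.05e-14 and 0.293 for cell cycle, 3.79e-05 and 0.361 for the stress response, 5.91e-10 and 0.293 for NF-kB, 0.0304 and 0.316 for autophagy, and 0.0452 and 0.361 for SAGA. They were 0.278 and 0.845 for stemness, 0.252 and 0.904 for interferon, 0.0499 and 0.726 for cholesterol synthesis, 0.343 and 0.954 for epithelial-mesenchymal transition, 0.0349 and 0.546 for Wnt, and 0.279 and 0.954 for oxidative phosphorylation. For other cell types the lowest was 0.358. The hypoxia target, glycolysis, cell cycle, hepatocyte, stress response and NF-kB lists passed without each library in turn, the highest value being 0.00811, for the stress response. Where not stated, the cause of a change was not tested. Of the values of the 57 named genes other than USP22, 642 kept direction and call, 35 kept direction without passing, 0 turned and 7 had no test. The calls of 14 of these genes were lost in at least 1 alternative, and those of 11 in a fit without a library. FASN (0.0535), XBP1 (0.0902) and GABARAPL1 (0.317) were lost only against a minimum fold of 1.5. In the simulation, at the depth and number of these libraries but with far fewer changed transcripts, 37.3% of 2-fold changes were recovered. The share in the data may differ.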

Other observations

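The lists of ribosome biogenesis, amino acid breakdown, metallothionein and phase-specific cell cycle genes, the tests on them and those on members with a single accession and on length and GC content were chosen after the results were seen, as were the genes named here. The tests of counts and spread were written before. Genes of ribosome biogenesis rose in part in the knockdown, with 26 of 43 tested higher, 0 lower and 17 not passing. Their median log2 fold change was 0.85. RRS1, an assembly factor of the large subunit, rose from 90.5 ± 37.6 to 315 ± 65.5 CPM (1.80 ± 0.25, adjusted p = 0.000356), and BOP1 from 54.4 ± 13.6 to 172 ± 45.5 CPM (1.66 ± 0.23, adjusted p = 0.000323). Nucleolin (NCL) rose from 930 ± 188 to 1794 ± 171 CPM (adjusted p = 0.00192). The list was written after 8 members had been seen among the changed transcripts. Without those 8, 18 of 35 members were higher and 0 lower, with a median of 0.59 and a camera p of 2.93e-08. With an estimated correlation the camera p was 0.0894. That setting has few degrees of freedom with 4 libraries and cannot decide on a shared rise of the group, which remains a hypothesis.

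Among enzymes of amino acid breakdown and the urea cycle, 12 of 23 tested were higher, 0 lower and 11 not passing, but 8 of the list had prompted it. TDO2, which opens the tryptophan ring, rose from 3.81 ± 0.0561 to 17.4 ± 2.91 CPM (2.19 ± 0.30, adjusted p = 0.000329). SDS, TAT and CPS1 belong to this list as well. Without those 8, 4 of 15 were higher and 0 lower, with a median of 0.37, a camera p of 0.0439 and p = 0.222 with an estimated correlation. Of the metallothioneins, 2 of 8 were tested. MT1X fell from 90.02 ± 39.7 to 10.2 ± 1.097 CPM (−3.14 ± 0.29, adjusted p = 1.99e-05), and MT2A was at −0.86 ± 0.35 (adjusted p = 0.106). Metallothionein genes are near-identical copies, so these values are uncertain. EPAS1, which encodes HIF-2α, had 1322 CPM in control and 966 CPM in knockdown cells (−0.45 ± 0.15, adjusted p = 0.053). HIF1AN, the asparagine hydroxylase that inhibits HIF, was lower (−0.50 ± 0.16, adjusted p = 0.0428), and VHL did not pass (adjusted p = 0.587). In 3 genes an accession rose and another fell. These were FAM19A5 (1.45 for NM_001082967.2 and −1.86 for NM_015381.6), HNMT (1.21 for NM_006895.2 and −1.56 for NM_001024074.2) and SEPTIN9 (1.81 for NM_001113491.1 and −1.30 for NM_006640.4).

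The hypoxia target list fell by a median of 2.05 on the log2 scale, while all libraries came from cells at 1% oxygen. Discarded isoform reads as the whole source were argued against by the 9 members with 1 RefSeq mRNA accession, whose median was −1.22. Of these, ADM, DDIT4, BHLHE40 and EPO did not pass. The decrease of the 9 was smaller than that of the list, so such reads as a part of the source stay open. A length or GC bias was argued against by the trend of fold change on both over all tested transcripts, which was weak and gave no member a value under −0.069. A weaker HIF response after loss of USP22 is a candidate explanation. It stays open beside a difference in oxygen, density or growth state between cultures and an effect of the hairpin other than on USP22, none of which was tested here.

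The cell cycle list rose by a median of 0.87. The 17 members with 1 RefSeq mRNA accession had a median of 0.957, which argues against discarded isoform reads as the whole source, and the trend on length and GC gave no member a value over 0.101, which argues against such a bias. A larger share of cells in G2 and M phase may contribute. The 18 members of those phases had a median 0.414 above that of the 11 members of G1 and S phase. Of the 18, 12 rose and 0 fell, and of the 11, 4 rose and 1 fell. The unadjusted camera p was 5.54e-12 for the 18 and 0.0212 for the 11, and 0.0477 and 0.407 with an estimated correlation. A two-sided permutation test between the groups across genes, which are not independent, gave p = 0.0946 (100000 permutations). A larger share of cells in G2 and M phase thus cannot be told apart from a general rise. A biological effect of USP22 loss on proliferation was not tested.

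Transcripts of genes with 1 RefSeq mRNA accession were called in 28.1% of cases, against 16.6% for genes with 2 and 11.75% for genes with 3 or more. Lower counts (a median of 2.94 CPM against 53.1) were argued against as the main source, because within 20 bins of mean CPM the difference was 13.2 percentage points (95% interval 11.2 to 15.2) against 16.3 without bins. A larger spread between libraries at equal counts was argued against by a ratio of spreads of 0.913 (0.876 to 0.952), with the larger spread on the side of 3 or more accessions in 7 of 20 bins. What kind of genes have a single accession, and how reads shared by isoforms were counted, stay open, and no biological explanation was tested.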
